A study of Homo sapiens with 8 samples.

How the data were processed

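Gene expression was measured on 8 single-colour Illumina bead arrays, each hybridised with biotin-labelled cRNA made from total RNA of SUM159 trailblazer cells, per the labels' protocols. The samples formed 4 groups of 2 arrays: cells with the empty pLIX vector and cells with the ΔNp63α-V5 pLIX vector, each without doxycycline or with 1 ug/ml doxycycline for 5 days, per the labels. Groups and replicate numbers were taken from the labels alone. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

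The values used were the probe intensities that the authors deposited, on a linear scale, for 47304 probes per array. The software and the normalisation method behind them are not given in the sources used here. Judged from the values, the arrays had been quantile normalised without background subtraction, since each array had a median of 113.5, a minimum of 89.2 and a maximum of 27456.4, and no sorted value lay more than 0.175 from the mean of the 8 arrays. A further deposited table of intensity values and detection p-values was not used here, because its 16 columns of per-sample values (8 of intensity and 8 of detection p) carry names that match no sample label. The plan fixed before the data were examined had named background correction from those detection p-values and a filter on them. The fallback written in that plan was used in their place: normexp background correction with an offset of 50 in limma 3.58.1, then log2, with no further normalisation because the arrays already shared a distribution. A fold change is therefore on the scale of normexp plus offset, which understates the change of low genes.

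A probe was kept if its deposited intensity exceeded 114.3 on both arrays of at least 1 group. That level is the mode of the deposited values, 106.9, plus 1.645 times 4.52, the SD of the values at or below the mode, mirrored around it. The form of this filter was chosen after the files were seen and before any test was run. It kept 23086 probes, and between 48.0% and 48.1% of the probes of each array lay above the level. Probe names came from the platform annotation supplied with the data: 30105 probes had 1 gene symbol, 8 had several and were left out of gene counts, and 17191 were not listed there and were left unnamed. An update of the symbols through 30066 matched Entrez gene identifiers changed 0 of them. Of the kept probes 16928 had 1 symbol, and the brightest kept probe of each gene was used, which gave 12385 genes, 3465 of them with more than 1 kept probe. No probe carried the symbol TP63 (0 probes), so the level of the induced gene was not analysed here and the labels could not be checked against it.

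limma was fitted with 1 mean per group over all 8 arrays, with 4 residual degrees of freedom and 7.48 prior degrees of freedom, followed by eBayes and Benjamini-Hochberg adjustment over the 12385 genes. Every adjusted p of a gene comes from this model, at a threshold of 0.05, and tests were two-sided. The median SE of a log2 difference between 2 groups was 0.116. There were 5 comparisons: doxycycline in each vector line, the difference between those effects (an interaction), and the vector lines against each other without and with doxycycline. Where a gene was below the background level on both arrays of the dimmer group, the fold is given as "at least", with the brighter group's mean set against the mean, per array, of the higher of the lowest log2 value above background and the probe's own value.

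Gene lists fixed before the data were examined numbered 26. They covered epithelial state, mesenchymal state, basal and squamous keratinocyte genes, hemidesmosome and laminin adhesion, the desmosome, reported p63 targets, trailblazer-associated genes, TGF-β response, YAP and TEAD targets, IL-1 and NF-κB inflammatory genes, interferon response, p53 targets, proliferation, the Notch and Wnt pathways, matrix proteases and inhibitors, nuclear-encoded oxidative phosphorylation, the mitochondrial ribosome, ATF4 and the integrated stress response, glycolysis and hypoxia, cholesterol biosynthesis, immediate early and heat shock genes, and markers of luminal breast epithelium, blood cells and endothelium. The list of mitochondrially encoded genes had 0 named probes and was not tested. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison, and again with an estimated correlation. With an estimated correlation camera uses the 4 residual degrees of freedom, and at the preset correlation degrees of freedom set by the number of genes. An adjusted p can therefore be higher with an estimated correlation even where the estimate lies below 0.01. Members were counted at the threshold over all genes and also adjusted over the list alone. A gene that belonged to several lists was counted under each.

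Named genes followed a rule fixed before the data were examined. A gene qualified when its adjusted p was under 0.05 and, outside the interaction, both arrays of 1 group lay above both of the other. Named were the 12 largest rises and 12 largest falls with doxycycline in the ΔNp63α line, 6 of each direction in the empty vector and in the difference, 8 of each between the lines without doxycycline, and up to 3 members of each list that passed in the ΔNp63α line and up to 2 in the empty vector. Where fewer qualified, all were named. Genes named outside this rule are said to have been chosen after their values were seen.

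Alternatives were no background correction, a normexp offset of 16, cyclic loess, no filter, a stricter filter (117.4 on all 8 arrays), the mean or the most variable probe of a gene, only the arrays compared, the replicate number as a block, eBayes with an intensity trend, robust eBayes, and the removal of each array in turn. Removal of an array leaves a group with 1 array, whose spread is then assumed to be that of the other groups. The filter and the choice of probe were redone at each removal, so a gene can be read from another probe there. The steps were tested on simulated data over 12385 genes: for doxycycline in the ΔNp63α line, 100 of 100 genes with a log2 change of 1 and 64 of 100 with a change of 0.50 were recovered, with 13 unchanged genes called. For the difference of effects the recovery was 95 of 100 and 8 of 100, with 3 unchanged genes called. For camera at the preset correlation on doxycycline in the ΔNp63α line, a simulation that raised 1 of the 25 lists by 0.3 called that list (adjusted p = 2.166e-26) and also 2 lists that had not been raised. In 100 repeats the raised list was called in 100 and any other list in 4, and in 100 repeats with no list raised any list was called in 2. Genes were simulated as independent, so these counts say nothing about genes that vary together. The noise of each gene was drawn from its variance after the shrinkage by eBayes. Such variances differ less between genes than those before shrinkage, so the recovery may be higher than on the real arrays. R 4.3.3 with the package data.table (version 1.17.8) and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.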

Results

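Expression was profiled in SUM159 trailblazer cells (SUM159T in the sample titles, where the empty-vector line is WT), a highly invasive subpopulation of a human breast cancer line, that carried a doxycycline-inducible lentiviral vector. The vector was either empty or encoded ΔNp63α, the N-terminally truncated isoform of the transcription factor p63 that marks basal epithelium, with a V5 tag. The design crossed the vectors with doxycycline, and the series title places p63 in the context of epithelial-to-mesenchymal states and collective invasion. Each of the 4 groups had 2 arrays. Spearman correlations over the kept probes ranged from 0.970 to 0.975 between arrays of the same group and from 0.954 to 0.975 between arrays of different groups. The leading principal component held 43.8% of the variance and placed the empty-vector arrays between -14.6 and -8.64, the uninduced ΔNp63α arrays at 1.46 and 2.77, and the induced ΔNp63α arrays at 15.7 and 21.7.

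In the ΔNp63α line, 5 days of doxycycline raised an inflammatory cytokine, a chemokine and several adhesion receptors. IL1A (probe ILMN_1658483), which encodes interleukin-1α, rose from a mean log2 intensity of 6.57 ± 0.17 to 9.24 ± 0.24 (SD, n = 2 arrays per group), a log2 change of 2.67 ± 0.14 (SE) and a 6.37-fold rise (limma adjusted p = 2.668e-06). CXCL8 (ILMN_2184373), a neutrophil-attracting chemokine, rose by 2.43 ± 0.35 from a level that differed between the uninduced arrays (8.18 ± 0.87, SD, n = 2). Against the empty vector, CXCL8 read -2.26 without doxycycline (limma adjusted p = 0.0527) and -0.46 with doxycycline in both lines (adjusted p = 0.472). The collagen-binding integrin subunit ITGA2 (ILMN_1665792) rose by 1.95 ± 0.13 and ITGB4 (ILMN_2334210), the β4 integrin of hemidesmosomes, by 1.83 ± 0.11, or 3.56-fold. Among the falls, SCG5 (ILMN_2065773), a neuroendocrine chaperone, changed by -1.83 ± 0.11 from 10.30 ± 0.11 to 8.47 ± 0.14 (SD, n = 2), and the Wnt antagonist DKK1 (ILMN_1773337) by -1.57 ± 0.20.

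The other rises among the 12 largest were GAL, the neuropeptide galanin, at a log2 change of 2.36, SERINC2 at 2.06, LITAF at 1.90, the keratin KRT75 at 1.87, the urate transporter SLC2A9 at 1.84, the steroid-reducing enzyme AKR1C2 at 1.80, the urea transporter SLC14A1 at 1.78 and the proteoglycan SDC1 (syndecan-1) at 1.74. SLC2A9 was below background on both uninduced arrays, so its rise was at least 3.30-fold. AKR1C2 has near-identical paralogs that a probe may not separate. The other falls were FAM13B at -1.51, the cadherin CDH6 at -1.45, the secreted glycoprotein FSTL1 at -1.37, the matricellular protein CCN1 at -1.29, the calcium-binding protein S100A4 at -1.27, PLAC8 at -1.23, XAGE2 at -1.18, PARM1 at -1.12, TENT5B at -1.10 and the homeobox gene PRRX2 at -1.09. XAGE2 belongs to a family of similar genes that its probe may not separate. A dimmer probe of DKK1 read -0.19, of CDH6 -0.10, of SLC2A9 0.18 and of SLC14A1 0.40, while a further probe of CXCL8 read 2.05, of ITGB4 1.05, of S100A4 -1.08, of PLAC8 -1.25 and of FAM13B -1.23.

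Across the 12385 genes tested, 338 (2.73%) changed with doxycycline in the ΔNp63α line at a limma adjusted p under 0.05, with 177 higher and 161 lower, and 41 rises and 20 falls exceeded 2-fold. The count was 120 without ΔNp63α no-dox replicate 1, 205 without ΔNp63α no-dox replicate 2 and 133 without ΔNp63α dox replicate 2, and it was 181 when only the 4 arrays compared were fitted and 500 with the replicate number as a block, although the labels do not say what that number stands for. S100A4 was not called without ΔNp63α no-dox replicate 1 (-1.07) or ΔNp63α dox replicate 2 (-0.84), and PARM1 was not called without ΔNp63α dox replicate 1 (-1.05). CCN1 moved to -0.95 without ΔNp63α no-dox replicate 1 and -0.77 without ΔNp63α dox replicate 2, and lost its call at an unchanged -1.29 without any single empty-vector array (no-dox replicate 1 or 2, dox replicate 1 or 2), with only the arrays compared and with robust eBayes. With no background correction calls were lost for CCN1 (-1.19), S100A4 (-1.24) and PARM1 (-0.86), and with only the arrays compared also for S100A4 (-1.27) and PARM1 (-1.12).

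**Figure D1:**
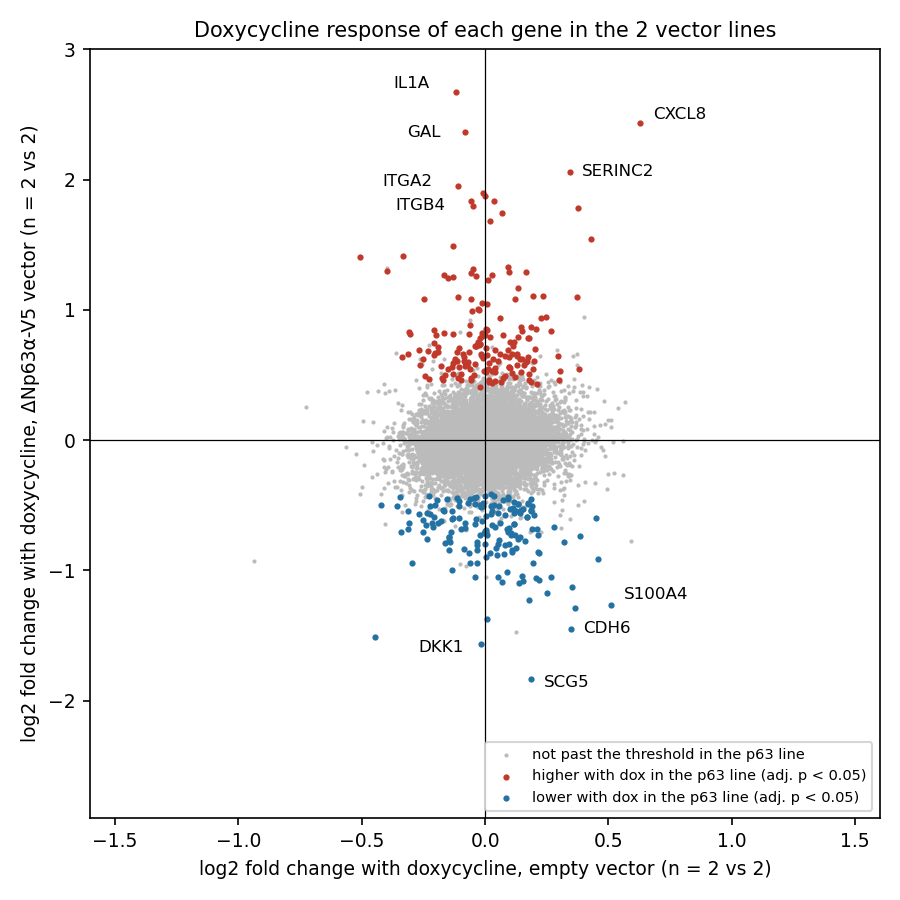
Each point is 1 of 12385 genes, with its log2 fold change with doxycycline in the empty-vector line on the x axis and in the ΔNp63α line on the y axis (2 arrays per group). Coloured points are the 177 genes that rose (red) and the 161 that fell (blue) in the ΔNp63α line, and IL1A lies highest at 2.67 on the y axis and -0.12 on the x axis.

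Among the lists tested, adhesion to the basement membrane had the largest median shift upward. Of 9 measured genes of the hemidesmosome and laminin list, 5 rose, 0 fell and 4 did not pass, and the same counts of 5 and 0 held when adjusted over the list alone. The members that rose furthest were ITGA2, ITGB4 and ITGA3 (1.09 ± 0.13), the last of which pairs with β1 integrin as a laminin receptor and read 0.41 on a dimmer probe. Of 19 measured reported p63 targets, 4 rose and 0 fell, and 8 rose when adjusted over the list alone. They included ITGB4, ITGA3 and the calcium-binding protein S100A2 (1.41 ± 0.19), so the integrins counted here are also members of the hemidesmosome list. The p63 target list does not separate targets reported as activated from targets reported as repressed. Its rises therefore do not measure activation of targets. Of 11 measured basal and squamous keratinocyte genes, 1 rose (S100A2, again shared) and 0 fell, and 2 rose over the list alone. A further 24 keratinocyte genes, among them KRT5 and IVL, had a probe that passed the filter in no group, the induced cells included. The same held for 14 reported p63 targets, among them KRT5 and TRIM29. Median log2 changes were 0.53 for the hemidesmosome list, 0.27 for the p63 targets and 0.15 for the keratinocyte genes. camera called these lists up at adjusted p = 1.060e-06, 4.807e-08 and 6.810e-04, and with an estimated correlation the adjusted p was 0.0559, 0.0559 and 0.0901. The estimated correlations were 0.00396, 0.00572 and 0.00452, all below the preset 0.01. The higher adjusted p thus does not come from a stronger correlation between the genes. Without ΔNp63α no-dox replicate 2 the keratinocyte list was not called (median 0.10, adjusted p = 0.222).

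The IL-1 and NF-κB inflammatory list also shifted up with induction. Of 18 measured members 5 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone. IL1A and CXCL8 led, followed by IL1B (1.29 ± 0.17), interleukin-1β, which lay below background on both uninduced arrays and rose at least 2.24-fold. The list median was 0.26 and camera gave adjusted p = 4.807e-08, while the adjusted p was 0.105 with an estimated correlation. The same list had a lower median in the ΔNp63α line than in the empty vector before induction (-0.26), and with doxycycline in both lines its median difference was -0.05.

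Most mesenchymal-state genes that passed the test fell. Of 32 measured, 1 rose, 9 fell and 22 did not pass, and 4 rose and 15 fell when adjusted over the list alone. S100A4 (-1.27 ± 0.23) and the growth factor receptor PDGFRB (-0.83 ± 0.10) fell, whereas ACTA2, smooth muscle actin and also a gene of myoepithelial cells, rose by 1.08 ± 0.15. VIM (-0.01), ZEB1 (-0.16) and ZEB2 (0.14) did not pass under either adjustment. SNAI2 (0.44) and PRRX1 (0.31) were among the 4 rises over the list alone, and TWIST1 (-0.43) among the 15 falls. These genes were named after their values were seen. The trailblazer-associated list, taken from earlier work on these cells and not chosen on these arrays, had 2 falls and 0 rises among 7 measured genes, and 5 falls and 1 rise over the list alone. Those that fell were the lipid phosphatase PLPP3 (-0.95 ± 0.11, and -0.23 on a dimmer probe) and the collagen-binding integrin subunit ITGA11 (-0.71 ± 0.16). ITGA11 also read -0.34 ± 0.16 with doxycycline in the empty vector. Its difference between the doxycycline effects of the lines did not pass (-0.37 ± 0.23, limma adjusted p = 0.741). Of 18 measured YAP and TEAD targets 5 fell and 0 rose, with the same counts over the list alone, led by CCN1 (-1.29 ± 0.29), CCN2 (-1.04 ± 0.20, and -0.70 on a further probe) and CRIM1 (-0.69 ± 0.13). The receptor tyrosine kinase AXL (-0.64 ± 0.12), named after its value was seen, was a fall of both the mesenchymal and the YAP list.

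The medians of the mesenchymal, trailblazer and YAP lists were -0.28, -0.47 and -0.20, and camera called them down at adjusted p = 4.147e-05, 0.0134 and 4.335e-05. With an estimated correlation the adjusted p was 0.0559, 0.317 and 0.0901. The estimates were -0.00187, 0.199 and 0.0261, so that of the mesenchymal list lay below the preset 0.01. The trailblazer list was not called without ΔNp63α no-dox replicate 1 (-0.33) or ΔNp63α dox replicate 2 (-0.33). CCN2 lost its call without ΔNp63α no-dox replicate 2 (-0.88) or ΔNp63α dox replicate 2 (-0.91), and CRIM1 without ΔNp63α no-dox replicate 1 (-0.73), no-dox replicate 2 (-0.64) or dox replicate 1 (-0.57). ITGA11 lost its call without ΔNp63α no-dox replicate 1 (-0.62), no-dox replicate 2 (-0.80) or dox replicate 2 (-0.51), and at an unchanged -0.71 without empty-vector dox replicate 1 or 2.

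Few classical epithelial genes could be measured. Of the 35 epithelial-state genes listed, 10 were measured and 0 passed in either direction, also when adjusted over the list alone. The lowest unadjusted p among them belonged to KRT8 (-0.43, limma adjusted p = 0.137) and AP1M2 (-0.28, adjusted p = 0.197), named after their values were seen and both lower. A further 23, among them CDH1 (E-cadherin) and EPCAM, had probes, but none above background on both arrays of any group. None of these genes therefore rose above background on both induced arrays, and changes short of that were not measurable here. The median was 0.00, the mean -0.05 and the camera direction down, at adjusted p = 0.499. In the desmosome list, 1 of 7 measured genes rose (DSG2, 0.65 ± 0.10) and 0 fell, with the same counts over the list alone and camera adjusted p = 0.0542. The DSG2 call depended on the probe: it was lost with the mean of its probes (0.54, adjusted p = 0.0605) and with the more variable probe (0.43, adjusted p = 0.416), and also without ΔNp63α no-dox replicate 1 (0.59). The desmosome list was called without empty-vector dox replicate 2 (adjusted p = 0.0308).

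**Figure D2:**
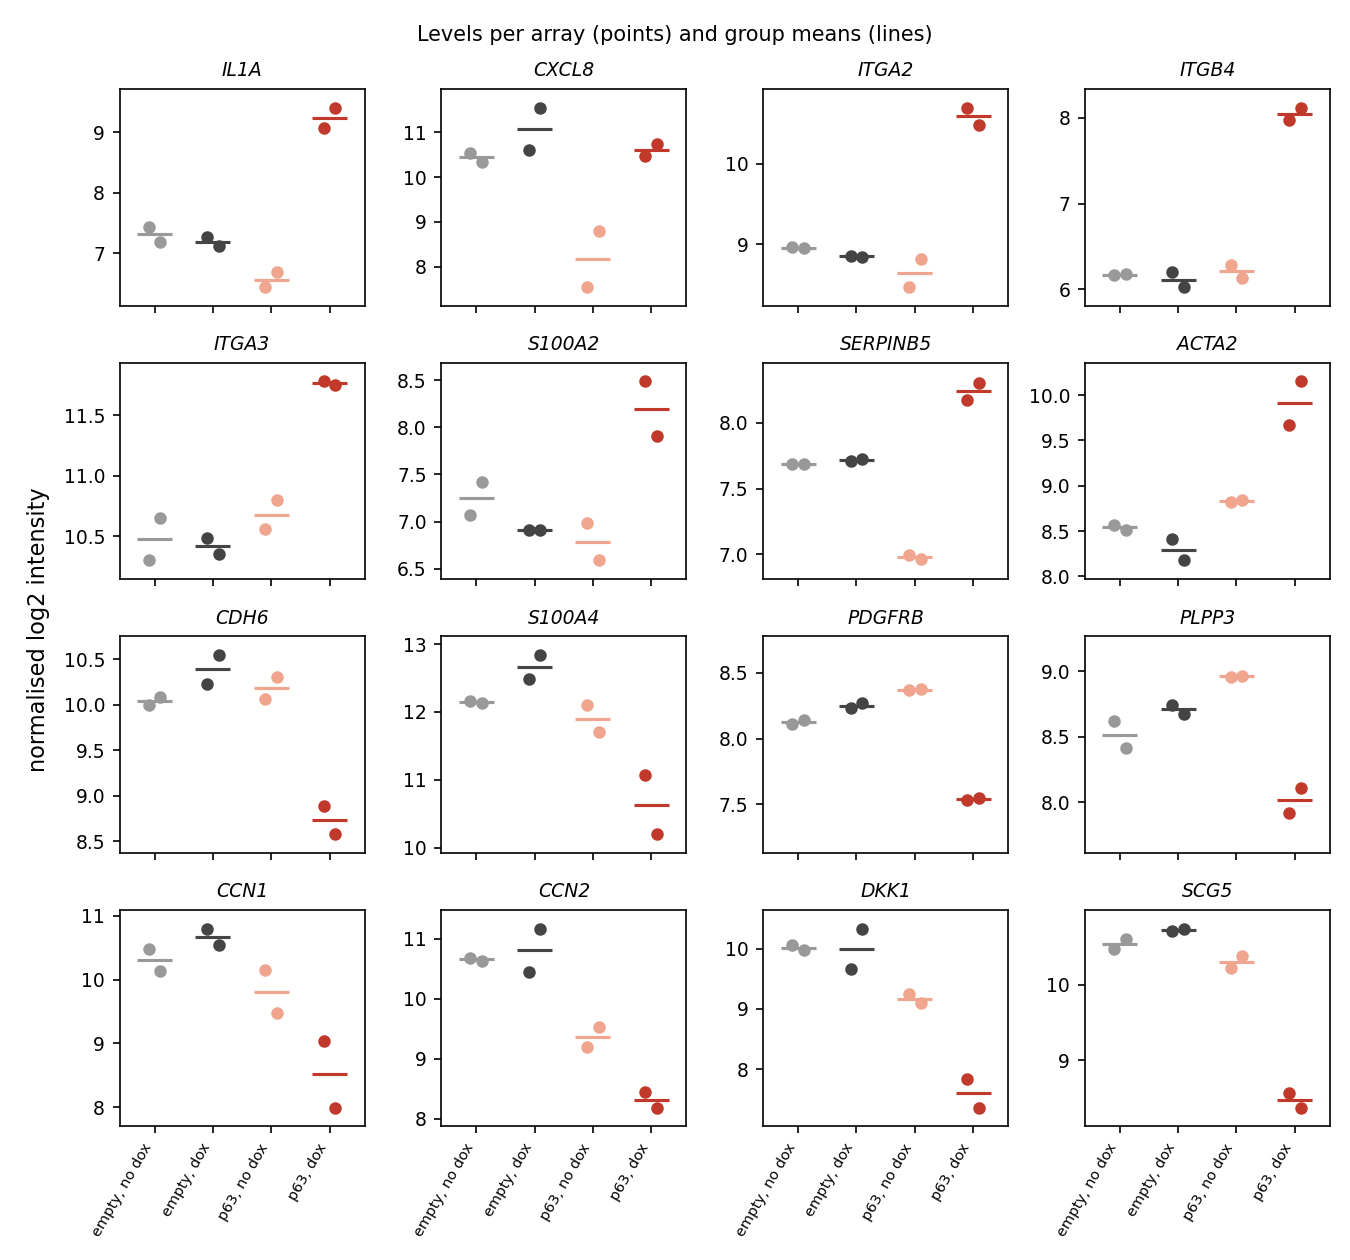
Points are the normalised log2 intensity of each array for 16 genes, by vector and doxycycline, and lines are group means of 2 arrays. IL1A, ITGA2, ITGB4, ITGA3 and ACTA2 are highest and CDH6, S100A4, PDGFRB, PLPP3 and SCG5 lowest in the induced ΔNp63α group, while CXCL8 at 10.6 there lies near the empty-vector level.

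Several signalling lists had single members that passed without a call for the list. In the TGF-β response list, 1 of 20 measured genes rose (ID1, an inhibitor of differentiation, 1.29 ± 0.20) and 3 fell, including the matrix protein TGFBI (-0.73 ± 0.11) and the ligand TGFB2 (-0.61 ± 0.13), with 3 rises and 6 falls over the list alone and camera adjusted p = 0.222. The Notch target HES1 rose by 0.81 ± 0.11 as 1 of 15 measured Notch genes, with 0 falls, 1 rise over the list alone and adjusted p = 0.222. DKK1 was the 1 fall among 20 measured Wnt genes, with 0 rises, 1 rise and 2 falls over the list alone and adjusted p = 0.342. Of 19 measured matrix proteases and inhibitors, 3 rose and 0 fell, with the same counts over the list alone: the serpin SERPINB5 (1.27 ± 0.10), the plasminogen activator PLAT (0.82 ± 0.14) and MMP28 (0.46 ± 0.11, at least 1.17-fold), at adjusted p = 0.107. SERPINB5 rose from a level that was lower than in the empty vector before induction (-0.71). MMP28 turned to -0.11 without ΔNp63α no-dox replicate 1, and was not called without no-dox replicate 2 (0.37), dox replicate 1 (0.43) or dox replicate 2 (0.15) of that line, nor, at 0.46, without empty-vector no-dox replicate 1 or 2. The spread of the main MMP28 probe (SD 0.13 without and 0.04 with doxycycline, n = 2) does not allow -0.11 or 0.15 on removal of 1 array. Another probe was therefore read in those cases, so those values compare probes as well as arrays. Without ΔNp63α no-dox replicate 1 or dox replicate 2, calls were lost for ID1 (1.09 and 1.06), TGFB2 (-0.47 and -0.50) and PLAT (0.59 and 0.74). With no filter MMP28 was read from another probe, which had not passed the filter, and the call was lost (4.165e-04). A dimmer probe of ID1 read 0.07.

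Among stress and growth lists, ATF5 fell (-0.65 ± 0.10) and the cystine transporter SLC7A11 rose (0.61 ± 0.13) out of 31 measured ATF4 and integrated stress response genes, with the same counts of 1 and 1 over the list alone (camera adjusted p = 0.522). The phosphatase DUSP5 (0.85 ± 0.14) and FOSB (0.48 ± 0.11) were the 2 rises, with 0 falls, among 21 immediate early and heat shock genes, where 2 rose and 1 fell over the list alone (median -0.03, mean 0.04, camera direction up, adjusted p = 0.729). The transcription factor E2F2 (-1.05 ± 0.21) was the 1 fall, with 0 rises, among 37 proliferation genes, with the same counts over the list alone (adjusted p = 0.0726). Without ΔNp63α no-dox replicate 1, calls were lost for DUSP5 (0.72), E2F2 (-0.91) and SLC7A11 (0.53), and without ΔNp63α dox replicate 2 for DUSP5 (0.73) and E2F2 (-0.88). E2F2 was also not called without ΔNp63α no-dox replicate 2 (-1.19) or, at -1.05, empty-vector no-dox replicate 2. SLC7A11 was also not called without ΔNp63α no-dox replicate 2 (0.69) or dox replicate 1 (0.42) or, at 0.61, empty-vector no-dox replicate 1 or 2. FOSB lost its call without each of the 8 arrays in turn, with values from 0.38 without ΔNp63α no-dox replicate 1 to 0.57 without ΔNp63α no-dox replicate 2. The proliferation list was called down without empty-vector dox replicate 1 or 2 (adjusted p = 0.00987 and 0.00949) or ΔNp63α dox replicate 1 (0.0285).

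The remaining lists had 0 members past the threshold over all genes except the blood cell markers, where the leukocyte integrin ITGB2 fell (-0.63 ± 0.12, and -0.97 on a further probe) and 0 rose among 8 measured (1 rise and 1 fall over the list alone, adjusted p = 0.777). That fall was not called without ΔNp63α no-dox replicate 1 (-0.54) or dox replicate 2 (-0.62). Over the list alone, 1 rise and 2 falls were counted among 23 p53 targets (adjusted p = 0.826, median -0.02, mean 0.01, camera direction up) and 1 fall among 28 glycolysis and hypoxia genes (0.301). Adjusted over the list alone, 0 changed among 26 interferon response genes (0.301), 30 oxidative phosphorylation genes (0.297), 28 mitochondrial ribosome genes (0.526), 19 cholesterol biosynthesis genes (0.337), 6 luminal markers (0.777) and 2 endothelial markers (0.729), where the value in parentheses is the camera adjusted p of the list.

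**Figure D3:**
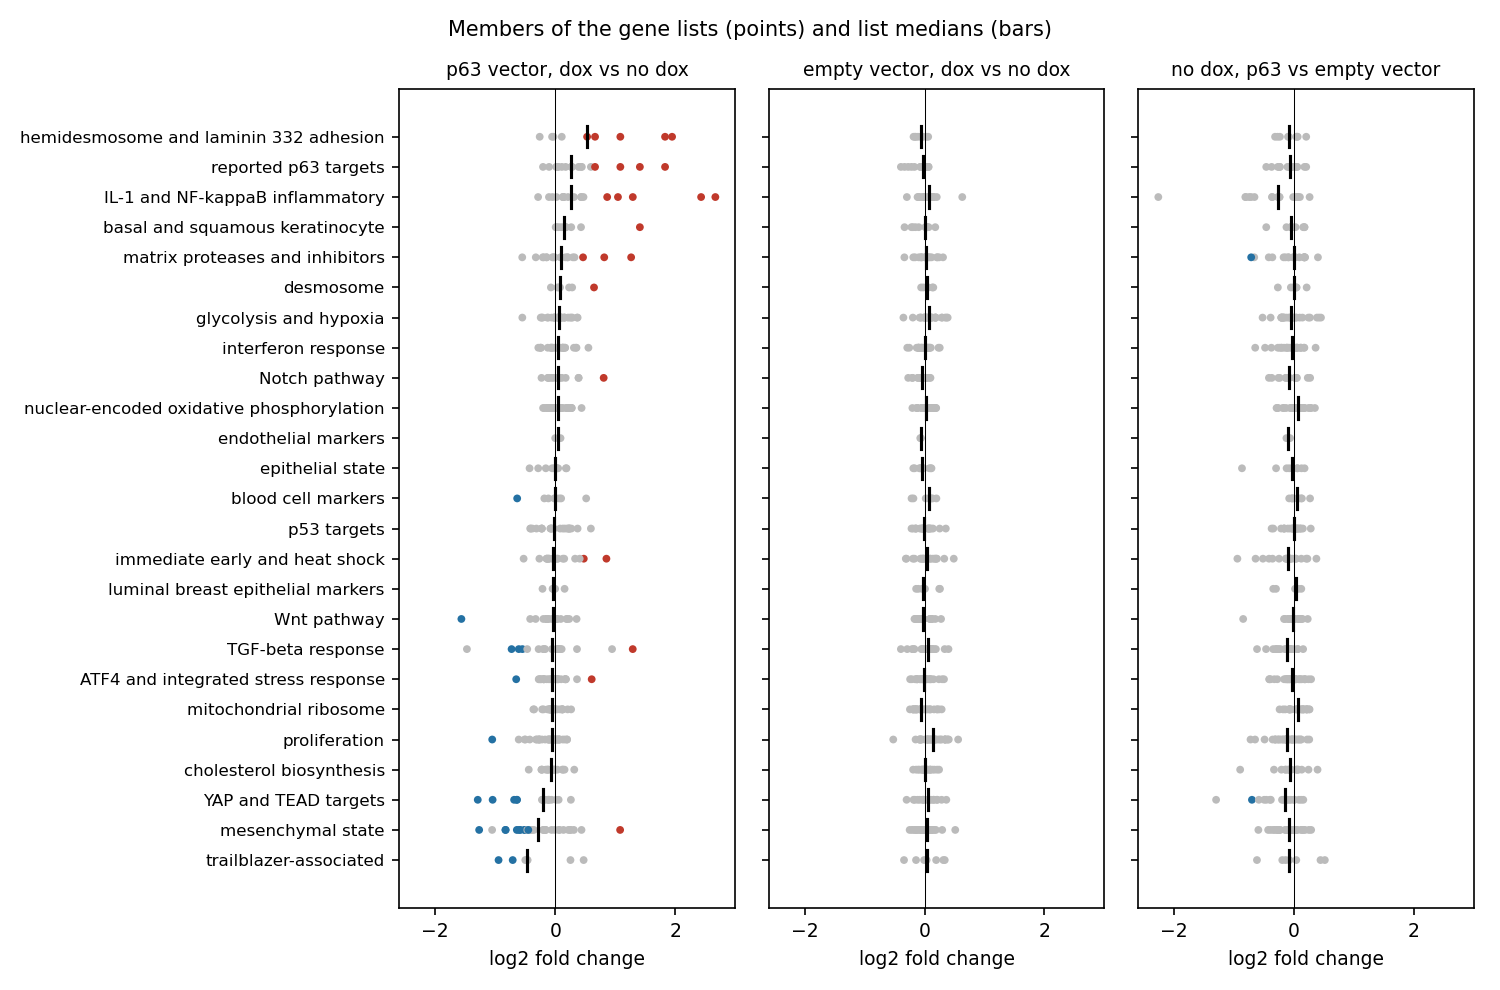
Points are log2 fold changes of list members in the comparison named above each panel, coloured red or blue where a gene was higher or lower at an adjusted p under 0.05, and bars are list medians. In the ΔNp63α line with doxycycline the medians run from -0.47 for the trailblazer-associated list to 0.53 for the hemidesmosome list.

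Doxycycline alone was examined in the empty-vector line. No gene passed the threshold there, so none was named: limma called 0 of 12385 genes, with a smallest adjusted p of 0.990, and 543 genes had an unadjusted p under 0.05 where 619 would be expected by chance. The genes that led in the ΔNp63α line read -0.12 ± 0.14 for IL1A, -0.11 ± 0.13 for ITGA2, -0.06 ± 0.11 for ITGB4 and 0.19 ± 0.11 for SCG5 (log2 change ± SE, n = 2 arrays per group). CXCL8 read 0.63 ± 0.35 and S100A4 0.51 ± 0.23. Over the 338 genes changed in the ΔNp63α line, the median absolute log2 change was 0.67 in that line and 0.11 in the empty vector, and 46.2% of them had the same sign in both.

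Proliferation genes and glycolysis and hypoxia genes had small upward shifts with doxycycline in the empty vector. The median was 0.14 over 37 proliferation genes and 0.08 over 28 glycolysis and hypoxia genes, with 0 members past the threshold over all genes or over the list alone. camera gave adjusted p = 0.00897 for both, and the adjusted p was 0.852 for both with an estimated correlation. The proliferation median turned to -0.05 without empty-vector dox replicate 2 (adjusted p = 0.134) and was not called without empty-vector no-dox replicate 2 (0.12, adjusted p = 0.0839). The glycolysis and hypoxia list was not called without empty-vector no-dox replicate 1 (0.06), dox replicate 1 (0.06) or dox replicate 2 (0.03). The other 23 lists tested were not called.

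The difference between the doxycycline effects of the lines estimates the change that doxycycline alone did not give. It was largest upward for IL1A (2.79 ± 0.20, SE), GAL (2.44 ± 0.18), ITGA2 (2.06 ± 0.18), SAA1 (1.91 ± 0.18), an acute-phase protein, LITAF (1.91 ± 0.20) and ITGB4 (1.89 ± 0.16), with n = 2 arrays in each of the 4 groups. It was largest downward for SCG5 (-2.02 ± 0.16), CDH6 (-1.80 ± 0.20), S100A4 (-1.78 ± 0.33), DKK1 (-1.55 ± 0.28), PARM1 (-1.48 ± 0.28) and XAGE2 (-1.43 ± 0.15). CXCL8 did not pass here (1.80 ± 0.49, limma adjusted p = 0.172), nor did CCN1 (-1.66 ± 0.41, adjusted p = 0.124). FAM13B did not pass either (-1.06 ± 0.27, adjusted p = 0.127) and read -0.45 ± 0.19 in the empty vector. Among list members named for induction, IL1B, CRIM1, TGFBI, E2F2, PLAT, CCN2, ID1 and SLC7A11 did not pass. Nor did MMP28, DSG2, FOSB, DUSP5, TGFB2, ATF5, ITGB2 and ITGA11. The limma adjusted p of these list members ranged from 0.0520 (IL1B) to 0.741 (ITGA11). Other SAA1 probes read 1.23 and 0.08, and a further probe read 1.04 for ITGB4, -1.39 for S100A4, -0.20 for CDH6 and -0.11 for DKK1. The further probes of ITGB4, CDH6 and DKK1 lay near background, so their values may understate a difference.

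In total 90 genes differed in their response, 56 with a higher and 34 with a lower effect in the ΔNp63α line (limma adjusted p under 0.05), and 87 of them were also among the 338 genes, all 87 with the same sign. The count was 42 and 33 without empty-vector no-dox replicate 1 and 2, 47 without empty-vector dox replicate 2, 52 without ΔNp63α no-dox replicate 1 and 52 without ΔNp63α dox replicate 2, and 59 with no background correction. It was 155 (86 higher, 69 lower) with the replicate number as a block. Calls were lost for S100A4, DKK1 and PARM1 without empty-vector no-dox replicate 1 (-1.79, -1.59 and -1.47), no-dox replicate 2 (-1.77, -1.50 and -1.49) and dox replicate 2 (-1.61, -1.22 and -1.32). Without ΔNp63α no-dox replicate 1, S100A4 (-1.58) and DKK1 (-1.47) were not called. DKK1 was also not called without ΔNp63α no-dox replicate 2 (-1.62) or dox replicate 2 (-1.31), nor PARM1 without ΔNp63α dox replicate 1 (-1.41) or replicate 2 (-1.55).

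The adhesion and mesenchymal lists differed between the lines in opposite directions. The hemidesmosome list (3 of 9 genes higher, 0 lower, 5 and 0 over the list alone, median 0.50), the p63 targets (3 of 19 higher, 0 lower, 5 and 0 over the list alone, 0.29), the IL-1 and NF-κB list (2 of 18 higher, 0 lower, 6 and 0 over the list alone, 0.24) and the keratinocyte list (1 of 11 higher, 0 lower, 2 and 0 over the list alone, 0.15) were called up at the preset correlation, the last 2 of them not with an estimated correlation (adjusted p = 0.163 and 0.101). The mesenchymal list (1 of 32 higher, 3 lower, 2 and 7 over the list alone, -0.27), the trailblazer list (0 of 7 higher, 1 lower, 0 and 2 over the list alone, -0.37), the YAP and TEAD targets (0 of 18 in either direction, 0 and 6 over the list alone, -0.18) and the proliferation list (0 of 37 in either direction, 0 and 1 over the list alone, -0.18) were called down at the preset correlation, the last 3 of them not with an estimated correlation (adjusted p = 0.299, 0.101 and 0.635).

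The camera adjusted p was 1.899e-08 for the hemidesmosome list, 1.296e-09 for the p63 targets, 1.991e-06 for the IL-1 and NF-κB list, 9.520e-04 for the keratinocyte list, 1.966e-05 for the mesenchymal list, 0.00311 for the trailblazer list, 1.171e-04 for the YAP and TEAD targets and 5.343e-04 for the proliferation list. With an estimated correlation the hemidesmosome list (adjusted p = 0.0434), the p63 targets (0.0434) and the mesenchymal list (0.0495) were still called. The proliferation list was not called without empty-vector dox replicate 2 (-0.02), the keratinocyte list without ΔNp63α no-dox replicate 2 (0.09), and the trailblazer list without ΔNp63α no-dox replicate 1 (-0.28) or dox replicate 2 (-0.18). The Notch list was called up without empty-vector no-dox replicate 1 (adjusted p = 0.0322) or dox replicate 2 (0.0290).

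Before induction the lines were compared to see what differed without doxycycline. The 6 genes that passed were all lower in the ΔNp63α line: FEZ1, a neuronal trafficking adaptor (-2.04 ± 0.29, SE, n = 2 arrays per group), the metallothionein MT1E (-1.92 ± 0.17), the homeobox gene PKNOX2 (-1.57 ± 0.19), the kinase PRKCH (-0.82 ± 0.10), SERPINB5 (-0.71 ± 0.10) and the LIM-domain protein AJUBA (-0.70 ± 0.10). The 3 other FEZ1 probes read -1.22, -0.09 and 0.05 and the other AJUBA probes -0.19 and 0.00, and MT1E belongs to a family of similar genes that its probe may not separate. limma called 0 genes higher and 6 lower, with 1240 genes at an unadjusted p under 0.05 where 619 would be expected by chance. The count was 0 without empty-vector no-dox replicate 1 and 1 without replicate 2. It was 37 (5 higher, 32 lower) when only the 4 arrays compared were fitted, 28 (2 higher, 26 lower) with an intensity trend and 27 (4 higher, 23 lower) with the replicate number as a block. It was 18 with a normexp offset of 16, 11 with no filter and 10 with cyclic loess, all of them lower, and 3 with no background correction. With the mean of their probes FEZ1 (-0.82) and AJUBA (-0.30) were not called, nor was FEZ1 with robust eBayes (-2.04), and with no background correction FEZ1 (-1.92), PKNOX2 (-1.23) and SERPINB5 (-0.56) were not.

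Each of these 6 calls was lost without empty-vector no-dox replicate 1, where FEZ1 read -1.86, MT1E -1.80, PKNOX2 -1.46, PRKCH -0.77, SERPINB5 -0.71 and AJUBA -0.71. Without empty-vector no-dox replicate 2 the call was lost for FEZ1 (-2.22), PKNOX2 (-1.69), PRKCH (-0.88), SERPINB5 (-0.71) and AJUBA (-0.69), and without ΔNp63α no-dox replicate 2 for FEZ1 (-1.50), PRKCH (-0.78), SERPINB5 (-0.70) and AJUBA (-0.73). Without ΔNp63α no-dox replicate 1 it was lost for PRKCH (-0.86), SERPINB5 (-0.73) and AJUBA (-0.67). FEZ1 also lost its call, at -2.04, without empty-vector dox replicate 1 or 2.

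Inflammatory and YAP target genes lay lower as groups in the uninduced ΔNp63α line. Of 18 IL-1 and NF-κB genes 0 passed over all genes and 7 were lower and 0 higher when adjusted over the list alone, with CXCL8 at -2.26 (limma adjusted p = 0.0527). Of 18 YAP and TEAD targets, 1 was lower (AJUBA) and 0 higher, and 6 were lower over the list alone, with CCN2 at -1.30 (adjusted p = 0.0527). The median was -0.26 for the IL-1 and NF-κB list, -0.15 for the YAP targets, -0.11 for 20 TGF-β response genes, -0.12 for 37 proliferation genes and -0.10 for 21 immediate early and heat shock genes. In the last 3 lists 0 genes passed over all genes, and over the list alone 0, 0 and 4 were lower. camera called the lists down at adjusted p = 3.323e-07, 3.522e-05, 0.00896, 0.0367 and 0.0367. With an estimated correlation the adjusted p was 0.366, 0.337, 0.423, 0.727 and 0.412.

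Single arrays decided some of these list calls between the uninduced lines. Without empty-vector no-dox replicate 1 the proliferation (-0.11) and immediate early (-0.03) lists were not called, and without empty-vector no-dox replicate 2 the proliferation list (-0.13) was not. Without ΔNp63α no-dox replicate 2 the TGF-β (-0.11), proliferation (-0.06) and immediate early (-0.11) lists were not called, and the ATF4 and integrated stress response list was called down (adjusted p = 0.0332). The mesenchymal list was called down without ΔNp63α no-dox replicate 1 (-0.12, adjusted p = 0.00876). The other 20 lists tested were not called.

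With doxycycline in both lines, the vectors differed at 1207 genes, 575 higher and 632 lower in the ΔNp63α line (limma adjusted p under 0.05), of which 43 and 67 exceeded 2-fold. IL1A was higher by 2.04 ± 0.14 and ITGB4 by 1.93 ± 0.11, while CCN2 was lower at -2.49 ± 0.20 and DKK1 at -2.39 ± 0.20 (log2 difference ± SE, n = 2 arrays per group), genes chosen after their values were seen. This comparison combines the effect of the insert with any difference between the lines, and 81.1% of the 1207 genes differed in the same direction without doxycycline, against 64.1% of the genes not called. The count was 387 without empty-vector dox replicate 2 and 409 without ΔNp63α dox replicate 2, and it was 718 when only the 4 arrays compared were fitted and 1659 with the replicate number as a block.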

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

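The tests of the IL-1 list members that rose, of expression before induction and of calls made on the doxycycline arrays alone were chosen after the results were seen, and the other tests were written down before. Results are listed here when the doxycycline effect differed between the ΔNp63α and the empty-vector line by limma's interaction test, or for a gene list by camera on that contrast. This held for 90 genes. Among the named genes the log2 difference of effects was above 0 for IL1A (2.79), GAL (2.44), ITGA2 (2.06), SAA1 (1.91), LITAF (1.91), ITGB4 (1.89), KRT75 (1.87), AKR1C2 (1.85), SLC2A9 (1.80), S100A2 (1.75), SERINC2 (1.72), SDC1 (1.68), SLC14A1 (1.40), ACTA2 (1.33), SERPINB5 (1.24), ITGA3 (1.14) and HES1 (1.01). It was below 0 for PDGFRB (-0.96), PLPP3 (-1.14), PRRX2 (-1.16), TENT5B (-1.24), FSTL1 (-1.38), PLAC8 (-1.40), XAGE2 (-1.43), PARM1 (-1.48), DKK1 (-1.55), S100A4 (-1.78), CDH6 (-1.80) and SCG5 (-2.02). Median differences of the gene lists that camera called at the preset correlation were 0.50 for hemidesmosome and laminin adhesion, 0.29 for p63 targets, 0.24 for IL-1 and NF-κB genes, 0.15 for basal and squamous keratinocyte genes, -0.18 for YAP and TEAD targets, -0.18 for proliferation, -0.27 for the mesenchymal state and -0.37 for trailblazer-associated genes. Of these 8 lists 5 were not called with an estimated correlation, at adjusted p = 0.101 for the keratinocyte list, 0.101 for the YAP list, 0.163 for the IL-1 list, 0.299 for the trailblazer list and 0.635 for the proliferation list.

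The IL-1 and NF-κB list was lower in the uninduced ΔNp63α line and shifted up with induction, and both comparisons share the uninduced ΔNp63α arrays. A single such array is argued against, since the list stayed low without either of them (higher camera adjusted p = 3.219e-05, with a range of 1.278e-07 to 3.662e-05 over the removal of each array and 0.366 with an estimated correlation). For the list as a whole the shift may be a return to the empty-vector level, because with doxycycline the median difference between the lines was -0.050 (camera adjusted p = 0.672). A return alone is argued against for 2 of the 4 risen members measured above background in the empty vector with doxycycline, IL1A (2.04) and SOD2 (0.79), which stood above that line. For the other 2, CXCL8 (-0.46) and CXCL2 (0.01), which did not pass there, it stays open. The risen members were picked by their rise on the same induced arrays. Chance high values on those arrays would therefore favour a level above the empty vector. IL1B stood above the empty vector in the same way (at least 2.24-fold, adjusted p = 0.00127) but was not counted, since it was below background in the empty vector with and without doxycycline and in the uninduced ΔNp63α line, so a low starting level could not be measured for it. IL6, which had not risen, stood lower (-0.76). A culture difference that lowered both uninduced arrays stays open, as does an effect of ΔNp63α on this pathway, which the design names.

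More genes separated the lines with doxycycline (1207) than changed with doxycycline in the ΔNp63α line (338). A difference between the lines that was present before induction may add to the effect, since 81.1% of the 1207 genes differed the same way without doxycycline, as did 81.3% of 685 genes called with filter, probe choice and spread taken from the doxycycline arrays alone. The genes not called already had 64.1% and 65.5%, so part of that share may reflect a general difference between the lines or their arrays. Taken in the direction of each difference with doxycycline, the medians over the 1207 genes were 0.18 for the difference without doxycycline, 0.30 for the doxycycline effect in the ΔNp63α line and -0.089 for that in the empty vector. The effect in the empty vector went the opposite way for 75.6% of the 1207 genes, against 62.1% of the genes not called, and that in the ΔNp63α line went the same way for 91.7% against 66.7%. Each of these effects shares its doxycycline arrays with the comparison of the lines, so chance differences of those arrays raise both shares, and how much either adds to the gap stays open. Expression of ΔNp63α before induction cannot be told apart from a lasting difference between the lines, because the p63 targets had a median of -0.069 without doxycycline (camera adjusted p = 0.170) and the induced gene itself was not analysed here. Without empty-vector dox replicate 2 the counts were 387 and 341, and without ΔNp63α dox replicate 2 they were 409 and 133, so single arrays weigh on the size of the gap.

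In the ΔNp63α line with doxycycline, 9 of 32 measured mesenchymal genes fell and 1 rose (list adjusted p = 0.0559 with an estimated correlation), while 0 of 10 measured epithelial genes passed in either direction. Without the filter on dim probes, 0 of 33 epithelial genes passed and their mean log2 change had an upper 95% bound of 0.023. The bound set beforehand was met, but 23 of the 33 genes were not above background, where changes are compressed. A rise of dim epithelial genes that does not lift both induced arrays above background therefore cannot be told apart from no rise. An effect of ΔNp63α on these genes, which the design names, stays open and was not tested further.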

How the results depend on the processing

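The normexp offset of 16 and the stricter filter were chosen after the data were seen, and all other alternatives before. Of 65 named gene results, 40 kept direction and call under every setting run, 25 lost the call under at least 1, and 1 reversed (MMP28, -0.11 without ΔNp63α no-dox replicate 1, where another probe was read, with a range up to 0.46 over the removal of each array). Apart from the removal of arrays, calls lost numbered 16 with no background correction (for induction CCN1, CCN2, S100A4, PARM1, E2F2, ITGA11, TGFB2, SLC7A11, FOSB and MMP28, in the difference PARM1, DKK1 and S100A4, between the uninduced lines FEZ1, PKNOX2 and SERPINB5), 9 with only the arrays compared (CCN1, S100A4, PARM1, ITGA11, TGFB2, PLAT, SLC7A11, FOSB and MMP28), 6 with the mean of probes (AJUBA, FEZ1, CCN2 and DSG2, and DKK1 and S100A4 in the difference), 3 with the most variable probe (DSG2, FOSB and MMP28), 2 with robust eBayes (CCN1 and FEZ1), 1 with no filter (MMP28) and 1 with the stricter filter (FOSB). The proliferation median in the empty vector also reversed (-0.053 without empty-vector dox replicate 2, with a range up to 0.30). Where 1 array at a time was removed, genes changed with doxycycline in the ΔNp63α line ranged from 120 to 341, differences of effects from 33 to 99, genes between the lines from 0 to 9 without and from 387 to 1173 with doxycycline, and lists called from 0 to 2 in the empty vector and from 3 to 6 between the uninduced lines. The empty vector gave 0 genes under every setting run. With only the arrays compared, counts were 181, 37 and 718 for induction and for the lines without and with doxycycline (against 338, 6 and 1207). With no background correction they were 59 for the difference of effects and 3 between the uninduced lines, where cyclic loess gave 10, no filter 11, the offset of 16 gave 18 and the intensity trend 28. The cause of these shifts was not tested. With an estimated correlation 0, 0, 3 and 0 lists were called for induction, the empty vector, the difference and the uninduced lines, against 7, 2, 8 and 5. With the replicate number as a block, counts were 500, 155 and 27 (4 of them higher) for induction, the difference and the uninduced lines. The labels do not say what the replicate numbers stand for, and with 2 numbers a pairing could not be settled: differences between replicates 1 and 2 correlated at 0.43 between the ΔNp63α groups, 0.21 between the empty-vector groups and 0.04 to 0.19 across lines. Not run were settings that need detection p-values, median scaling (the arrays already share a distribution), the deposited table as an alternative (it is the main source) and the slide as a block (not given in the sources used here). Signal over background limits the dim genes, since about 48.0% of probes exceeded the background level.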

Other observations

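Genes outside the named set, chosen after their values were seen, also separated the lines with doxycycline. The sterol exporters ABCA1 (1.58 ± 0.10) and ABCG1 (1.61 ± 0.18), the lipocalin APOD (1.63 ± 0.12) and the polyamine-acetylating enzyme SAT1 (1.71 ± 0.15) were higher in the ΔNp63α line (log2 difference ± SE, n = 2 arrays per group, limma adjusted p from 1.258e-05 to 3.402e-04). All 4 also rose with doxycycline within that line, by 0.82 for ABCA1, 0.83 for ABCG1, 1.49 for APOD and 1.30 for SAT1. The list of 19 cholesterol biosynthesis genes had a median difference of -0.11 between the lines with doxycycline (camera adjusted p = 0.263).

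On the lower side were the imprinted non-coding RNA H19 (-1.42 ± 0.14), the neuronal protein BEX1 (-2.05 ± 0.24), and EDN1, the vasoconstrictor endothelin-1 (-1.59 ± 0.19). H19 (-1.05) and BEX1 (-1.06) also fell with doxycycline in the ΔNp63α line. EDN1 did not pass within that line (-0.31, adjusted p = 0.531) or between the lines without doxycycline (-1.16, adjusted p = 0.0562). The matrix protein THBS1 was lower with doxycycline between the lines (-1.90 ± 0.36) and did not pass within the ΔNp63α line (-1.47, adjusted p = 0.0570).

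camera called 8 of the 25 lists in this comparison at the preset correlation and 0 with an estimated correlation, whose adjusted p is given second. Lower in the ΔNp63α line were the YAP and TEAD targets (median -0.55, adjusted p = 5.740e-09 and 0.0580), the mesenchymal list (-0.36, 3.324e-07 and 0.0580), the proliferation list (-0.27, 4.464e-06 and 0.556), the TGF-β response list (-0.23, 0.00450 and 0.399) and the trailblazer list (-0.69, 0.0108 and 0.399). Higher were the p63 targets (0.22, 4.460e-05 and 0.0669), the hemidesmosome list (0.23, 5.175e-05 and 0.0669) and the keratinocyte list (0.22, 0.00311 and 0.129).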
